A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

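RNA from leaves of 5-week-old soil-grown rice was sequenced on an Illumina instrument as strand-specific total RNA and mRNA libraries, per the labels' protocols. Water was withheld after soil water had been set to about 75%. The submitters' processing notes name FastQC 0.10.0, Trimmomatic 0.32, HISAT2 2.0.5, Bowtie2 2.2.6, StringTie 1.3.3b and the build IRGSP-1.0, with no role, order or strand setting. The authors deposited 1 table per library kind, with FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) per transcript and library, per the file headers. The same tables hold deposited log2 values, and from the values these are log2(FPKM + 1) after quantile normalization over the 4 libraries of a table. Their sorted values were equal within 0.01 for 100% of total RNA and 98.9% of mRNA entries. Each entry has FPKM above 0 in at least 1 library of its table. The deposited fold and mean columns were not used.

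FPKM values were summed over the transcripts of each gene. Each drought day was compared with the well-watered library of the same table as the log2 ratio of FPKM + 1, which understates differences of genes with low values. Genes in both tables with a mean of at least 1 FPKM in each were kept. A gene was called higher or lower when the ratio was at least 1, or at most -1, in both library kinds. The rule has no test, since each group holds 1 library. The low values give a step of FPKM times length, at which 8.58% to 12.9% of low values sit. Taking this step as 1 fragment is an assumption, and it puts 1 FPKM of a transcript of median length at 23.8 to 35.7 fragments, with 95% exact Poisson limits of 15.4 to 35.7 in the shallowest library. These limits cover counting error only.

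Gene lists (36 with at least 1 gene in the files) were fixed before the data were examined, by locus or by words in the file descriptions. Symbols in the lists by locus were recalled from general knowledge, and 2 loci were excluded because their description contradicted the symbol. For 6 description lists, exclusions were added from the text of the descriptions before values were looked at. The description list of seed storage proteins also takes in an immunoglobulin-domain gene by its wording. A RefSeq table of another assembly matched 1 gene identifier and was not used. A list's median was ranked among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries.

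The genes named were set by a rule written before the data were examined. It takes the 6 highest and 6 lowest described genes per day by the smaller ratio, the 2 members of each list with the largest mean ratio on a day, 7 drought genes, 2 pairs of a noncoding and a neighbouring coding gene, the 5 highest and 5 lowest noncoding genes on day 3, and the 5 highest genes on each side of the comparison of library kinds. Not all genes the rule takes are printed. Genes named outside it are said to be so or stand under the clock test. That test was set beforehand on LHY, PRR1 and GI, and PRR73 was added after its values were seen.

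Before use, the calculation was tested on simulated data for drought day 3 with 18113 genes and a noise SD of 0.111 (log2). This SD stands for 1 log2 value and was taken from the interquartile range of the difference between the library kinds on day 1. It holds no difference between plants and no added counting error at low values. The plain SD of the difference between the ratios of the 2 kinds was 0.291 on day 1 and 0.435 on day 3. These are SDs of a difference of ratios, so they are not on the scale of 0.111. The size rule recovered 4 of 67 genes made 2-fold different, 59 of 67 made 4-fold and 64 of 66 made 8-fold, and called 0 of 17913 unchanged genes. A list of 30 genes made 2-fold higher lay at the percentile 100 and a list of 30 unchanged genes at 14.5. On the same simulation limma recovered 67, 67 and 66 genes and called 8 unchanged ones. The simulation checks the calculation and gives no error rate for calls between real plants.

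Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, median-ratio scaling within each table, each library kind alone, and limma 3.58.1 in R 4.3.3 with library kind as a block (3 residual degrees of freedom, Benjamini-Hochberg adjusted p under 0.05). Median-ratio size factors were taken from genes above 0 in every library of a table. They were first computed from genes of both tables and in a trial from the filtered genes. When the counts differed, the factors were set to the definition fixed beforehand, and 5 other gene sets for them were added as alternatives. Another 2 scalings were added after seeing the data, the deposited quantile-normalized values and FPKM with the 10 most abundant genes left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.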

Results

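Leaf RNA of japonica rice (variety Ilmi) was compared between well-watered plants and plants left without water for 1, 2 or 3 days. Each of the 4 treatments was sequenced as a total RNA library and as a poly(A)-selected mRNA library, which gave 8 libraries and 1 library per treatment and library kind. There is no replicate, so differences are named by a fixed rule of size with no p-value, and a limma fit that takes the library kinds as replicates stands only among the alternatives. The labels do not say whether the 2 library kinds came from the same RNA, so their likeness may be technical. There are 36538 transcripts of 30263 genes in the deposited total RNA values and 34770 transcripts of 28506 genes in those of mRNA, all on chromosomes 1 to 12 of the IRGSP-1.0 build. FPKM values summed to between 678548 and 755487 per library, and if the smallest step of FPKM times length is 1 fragment, the libraries held 16.3 to 24.6 M fragments. Of 27626 genes in both tables, 18113 had a mean of at least 1 FPKM in each, 17815 of them protein-coding and 298 noncoding.

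The first question was how leaf transcripts differ after each day without water. On day 1, 1256 genes were at least 2-fold higher than in the well-watered libraries in both kinds and 446 at least 2-fold lower. On day 2 the counts were 2627 and 2008, and on day 3 they were 3290 and 4699. The share of higher among called genes was thus 73.8% on day 1 and 41.2% on day 3, while under median-ratio scaling it was 56.8% on day 1 (891 higher, 677 lower) and 55.8% on day 3 (4408 higher, 3488 lower). Under the deposited quantile normalization, an alternative chosen after seeing the data, it was 55.8% on day 1 (964 and 765) and 47.9% on day 3 (3439 and 3742). With a pseudocount of 5, which gives low genes less weight, the counts were 648 and 239 on day 1, 1643 and 1187 on day 2 and 2511 and 2450 on day 3. The direction in which more genes differed on day 3 is therefore not settled by these values. The median gene stood at 0.23, 0.11 and -0.24 (log2) on days 1, 2 and 3 in the total RNA libraries and at 0.17, 0.06 and -0.39 in the mRNA libraries. Differences of at least 8-fold numbered 79 higher and 14 lower on day 1, and 883 higher and 714 lower on day 3.

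**Figure D1:**
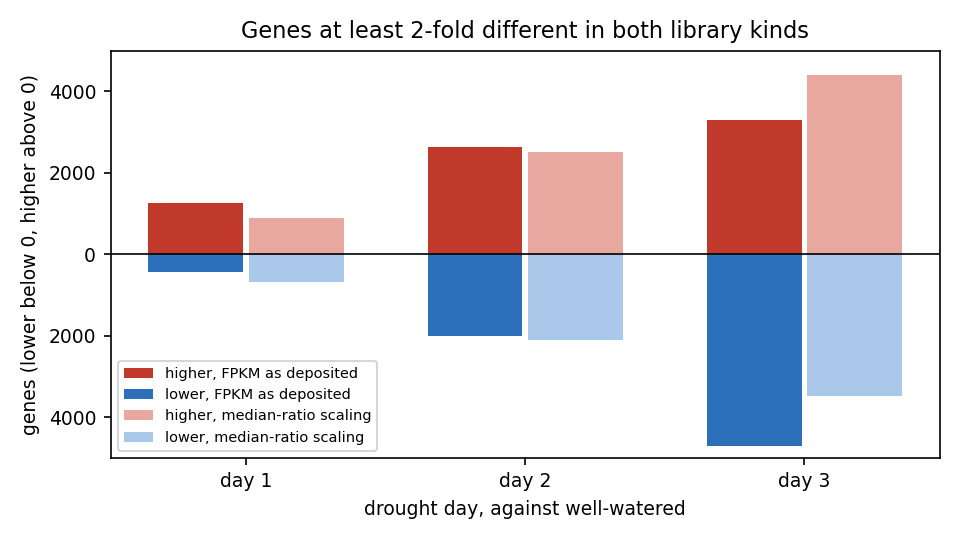
Number of genes at least 2-fold higher (above 0) or lower (below 0) than well-watered in both library kinds, per drought day, for deposited FPKM (dark bars) and median-ratio scaling (light bars). On day 3 the deposited scale gives 3290 higher and 4699 lower genes and the other scale 4408 and 3488.

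The 2 library kinds gave close answers. Across genes, which are not independent replicates, their log2 ratios correlated with Pearson's r of 0.916 on day 1, 0.968 on day 2 and 0.973 on day 3. The genes called in opposite directions by the kinds were Os07g0173700 on day 1, Os04g0676700, Os05g0499800 and Os09g0131400 on day 2, and Os05g0495300, Os07g0173700, Os07g0581400 and Os12g0283900 on day 3, all named after their values were seen. If the kinds were independent, 731 genes would be called higher and 1675 lower on day 3. Of the 1568 genes higher on day 1 in the total RNA table, 1201 were higher on day 3 in the mRNA table, against 303 for independent lists. Of 542 lower genes, 484 were lower on day 3, against 180. These tables share no library, so the overlap does not come from a shared control library, although it may come from shared plants.

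Transcripts of late embryogenesis abundant (LEA) proteins and dehydrins, which protect cells that lose water, were higher than those of any other fixed list on day 3. All 14 measured members of the abscisic acid (ABA)-responsive LEA list were at least 2-fold higher on day 3 in both kinds, after 7 on day 1 and 12 on day 2. The list median was 6.81 in total RNA and 7.06 in mRNA on day 3, at the percentile 100 of random lists matched on expression. In the wider list of LEA proteins and dehydrins by description, 18 of 23 measured members were higher and 2 lower on day 3. Its medians were 5.11 and 5.56. Os11g0454300, described as water-stress inducible protein RAB21 (chromosome 11, 15342877 to 15343671), stood at 1.50 FPKM in the well-watered total RNA library and at 49.3, 473 and 6737 FPKM on days 1, 2 and 3. In mRNA it stood at 0.726, 46.5, 418 and 7279 FPKM, and on day 3 it was the most abundant gene of both libraries. The LEA protein gene Os05g0542500 (LEA3) was at 0.609 FPKM when watered and at 58.2, 666 and 4634 FPKM in mRNA. The dehydrin genes Os11g0454200 (RAB 16B) and Os11g0451700 had day 3 ratios of 10.36 and 9.64 in total RNA and 10.36 and 9.40 in mRNA.

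Genes of ABA synthesis and signalling differed in both directions. ABA is the hormone that closes stomata under drought, and carotenoid-cleaving oxygenases make its precursor. Of 9 measured genes of ABA synthesis and breakdown, 3 were higher and 5 lower on day 3. Os02g0704000, a carotenoid oxygenase gene on the list as NCED1, was at 1056 FPKM when watered and at 409, 82.3 and 3.27 FPKM on the drought days in total RNA, and its day 1 call was lost under quantile normalization. Os07g0154100 (NCED4) was at 0.199, 2.52, 20.4 and 257 FPKM, and Os03g0645900 (NCED3) at 2.37, 5.79, 12.7 and 66.7 FPKM, although the day 1 call of NCED3 was lost under each other scaling and those of both genes with a pseudocount of 5. Clade A protein phosphatases 2C, which restrain ABA signalling, were higher in 7 of 9 members on each drought day. Their median ratio was 1.72 and 1.70 on day 1 and 3.48 and 2.81 on day 3 (total RNA, mRNA), and Os05g0572700 (PP2C51) reached 6.43 and 7.19 on day 3. Of 10 SnRK2 kinases, some of which ABA activates, 4 were higher on day 3. Among them were SAPK1 (Os03g0390200) at 3.53 and 3.52 and SAPK9 (Os12g0586100) at 3.51 and 3.31. SAPK7 (Os04g0432000) was lower at -1.33 and -1.11, a call lost under median-ratio and quantile scaling and with a pseudocount of 5. Of 3 measured ABA receptors, Os03g0297600 (PYL6) was lower on each drought day, at -2.23 and -2.33 on day 3, its day 1 call being lost with a pseudocount of 5.

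Transcription factors linked to drought were mostly higher by day 3. Of 18 measured, 6 were higher and 2 lower on day 1, and 14 were higher and 1 lower on day 3, with medians of 2.89 and 2.88. The NAC factor gene Os03g0815100 was at 37.1 FPKM when watered and at 98.8, 332 and 1102 FPKM afterwards in total RNA. The bZIP gene Os02g0766700 (bZIP23), which acts in ABA responses, had ratios of 1.80, 2.68 and 3.66. Os11g0126900 (NAC10) was highest on day 2, with 80.5 FPKM against 0.855 when watered and 30.2 on day 3. Os06g0127100, described as DREB1C, was below 2 FPKM until day 2 and at 75.3 FPKM on day 3. The gene on the list as DREB1B (Os09g0522000) was lower on each day at -2.16, -2.07 and -1.27 in total RNA, but all 3 calls were lost with a pseudocount of 5 and the day 3 call also under median-ratio and quantile scaling. By description, 15 of 28 NAC genes, 23 of 52 WRKY genes and 14 of 28 AP2/ERF genes were higher on day 3 and 4, 8 and 3 were lower.

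Of 8 measured osmolyte genes, 1 was higher on day 1, 3 were higher and 3 lower on day 2, and 5 were higher and 1 lower on day 3. The day 3 medians were 2.82 and 2.35, while the day 1 median changed sign between kinds and scalings (0.08 and -0.07, median-ratio -0.13 and -0.24). Os05g0455500 (P5CS1), which makes proline, was higher from day 1, at 51.4 FPKM against 9.61, and the proline-degrading Os10g0550900 was lower on day 2 at -1.99 and -1.97 and on day 3 at -1.65 and -1.70. A gene described as water stress-induced WSI76, Os07g0687900 (galactinol synthase), was at 13.5 FPKM when watered and 965 FPKM on day 3 in total RNA.

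Transcripts for photosynthesis were lower, most of all on day 3. Of 15 chlorophyll a/b-binding protein genes, 4 were lower on day 1, 12 on day 2 and 13 on day 3, with day 3 medians of -5.51 and -5.49. Photosystem subunit genes were lower in 24 of 27 members on day 3 (medians -4.68 and -4.67), Calvin cycle enzyme genes in 6 of 7 (-3.93 and -4.17) and Rubisco small subunit genes in 4 of 4 (-7.65 and -7.93). Each of these lists kept its sign on day 3 under median-ratio and quantile scaling. Os01g0600900, a chlorophyll a/b-binding protein gene, was at 6501 FPKM when watered and at 2450, 425 and 17.1 FPKM afterwards in total RNA, its day 1 call being lost under quantile normalization. Os12g0274700, a Rubisco small subunit gene, was at 3538 and 15.3 FPKM on those 2 ends, and Os02g0698000, which encodes phosphoribulokinase, at 672 and 10.5 FPKM. On day 3, 2 chlorophyll a/b-binding and 2 photosystem genes were not called, and 1 photosystem and 1 Calvin cycle gene were higher. The higher ones were Os07g0147550, a gene for a 10 kDa polypeptide of photosystem II, with ratios of 1.31 (a call lost with a pseudocount of 5), 5.04 and 3.87 in total RNA, and Os04g0266900, a transketolase-like gene, at 3.20 on day 3. The neighbouring Os07g0147500, which has a like description, went the other way at -8.67 on day 3, and how reads were shared between these genes is not given in the sources used here. Plastid ribosomal protein genes, whose products translate plastid messages, were lower in 2 of 54 members on day 1, 25 on day 2 and 41 on day 3 and higher in 1, 1 and 0, with day 3 medians of -1.87 and -2.14.

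**Figure D2:**
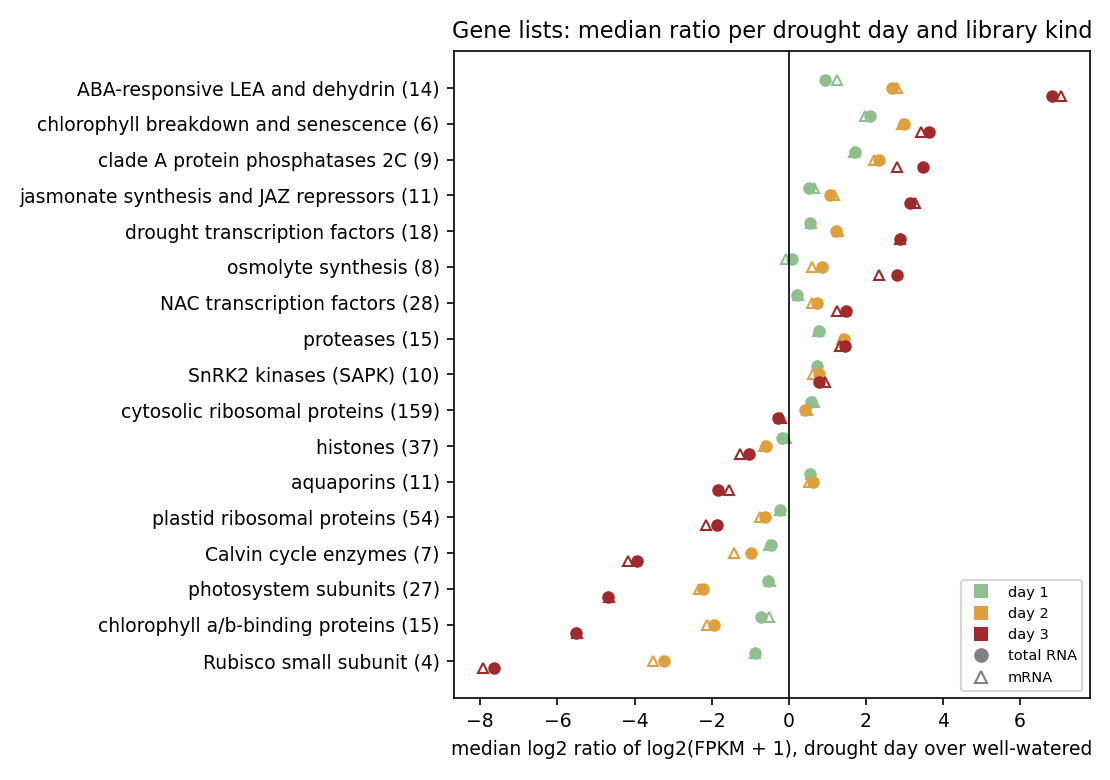
Median log2 ratio of log2(FPKM + 1), drought day over well-watered, for fixed gene lists (number of measured genes in brackets), by day (colour) and library kind (circles total RNA, triangles mRNA). ABA-responsive LEA genes lie at 6.81 and 7.06 on day 3 and Rubisco small subunit genes at -7.65 and -7.93. The sign of the cytosolic ribosomal list on day 3 turns under median-ratio scaling but not under quantile normalization.

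Genes of chlorophyll breakdown and leaf senescence were higher early. Of 6 measured, 5 were higher on day 1 and 6 on days 2 and 3, with medians of 2.10, 2.99 and 3.63 in total RNA. Os09g0532000 (SGR), the stay-green gene that starts chlorophyll breakdown, was at 42.6 FPKM when watered and at 209, 489 and 929 FPKM, and Os03g0327800, described as a NAC factor (NAP), was at 19.6, 21.6, 66.2 and 462 FPKM. Jasmonate synthesis and JAZ repressor genes were higher in 7 of 11 members on day 3 and lower in 2, with medians of 3.14 and 3.28. The TIFY-domain gene Os03g0180900 (JAZ11) was at 3.75 FPKM when watered and at 513 FPKM on day 3 in total RNA.

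Aquaporins, the water channels, were 1 of 11 higher on day 1, 3 higher and 1 lower on day 2 and 8 lower on day 3. Their medians were 0.55 and 0.58 on day 1 and -1.83 and -1.55 on day 3, with the same sign under median-ratio and quantile scaling. Os09g0541000 (PIP2-7) was at 1052 FPKM when watered and at 604, 81.1 and 41.9 FPKM. Os04g0233400 (PIP2-6) was at 25.4, 77.6, 112 and 10.6 FPKM, and its lower call on day 3 was lost under median-ratio and quantile scaling and with a pseudocount of 5. Cytosolic ribosomal protein genes stood at 0.58 and 0.66 on day 1 and at -0.28 and -0.21 on day 3, where the sign turned under median-ratio scaling (0.08 and 0.35) and stayed under quantile normalization (-0.63 and -0.45). Histone genes were lower in 17 of 37 members on day 3 and higher in 2, with medians of -1.03 and -1.27, and Os04g0253000 (histone H1) was at 975 FPKM when watered and 60.3 on day 3 in total RNA. On the deposited scale none of the 3 measured reference genes was called on a drought day. Their largest ratio was that of actin 1 (Os03g0718100) at 1.10 and 0.98 on day 3, close to the size rule in mRNA. The sign of the reference median on day 3 differed between scalings (0.02 and 0.08, median-ratio 0.39 and 0.65, quantile -0.31 and -0.34).

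Among single genes, 6 were taken on each side per day by the smaller of their ratios in the 2 kinds. Isocitrate lyase (Os07g0529000, chromosome 7, 20691213 to 20693521), which turns fatty acid carbon into sugar precursors, was the highest of these on day 1, at 3.58 FPKM when watered and at 342, 2243 and 1713 FPKM in total RNA. Malate synthase (Os04g0486950), its partner enzyme, was at 1.84, 138, 607 and 472 FPKM. Lysine-degrading Os02g0783625 was at 3.93, 161, 561 and 1597 FPKM, and the amino acid transporter Os04g0460300 was at 0.580, 66.8, 321 and 373 FPKM. A fructosyltransferase gene, Os02g0106100, was highest on day 2, with 224 FPKM against 1.56 when watered and 18.6 on day 3. A small heat shock protein gene, Os02g0758000, had the same course at 8.95, 106, 561 and 35.3 FPKM. The lowest on day 1 included the MYB gene Os05g0567600, at 109 FPKM when watered and 2.91 on day 1, and the A-type response regulators Os12g0139400 (59.5 to 2.07 FPKM) and Os02g0557800 (50.2 to 2.67 FPKM), which dampen cytokinin signals. On day 3 Os01g0615100, an inhibitor of subtilisin and chymotrypsin, was at 3326 FPKM against 2.46 when watered, and the chitinase gene Os05g0247100 at 1824 against 2.00. Of 8 measured antioxidant enzyme genes, a separate list, 3 were higher and 4 lower on day 3, with medians of -0.60 and -0.44. Median-ratio scaling gave -0.23 and 0.13. Catalase A (Os02g0115700) was at 313 FPKM when watered and 6.85 on day 3, and catalase B (Os06g0727200) at 34.5 and 437 FPKM. Neither was among the 6 highest or 6 lowest on day 3.

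**Figure D3:**
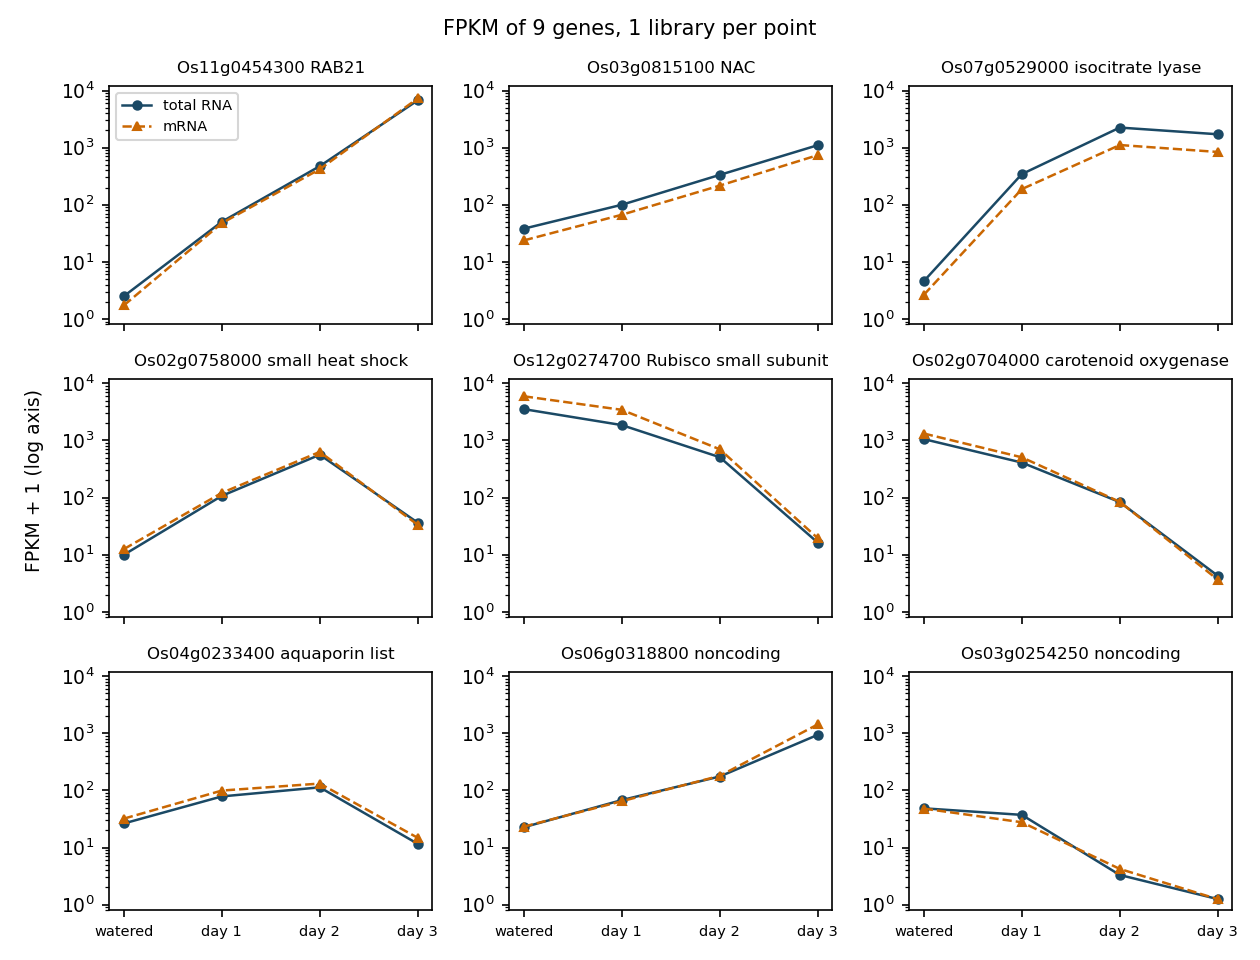
FPKM + 1 on a log axis of 9 genes in the well-watered and drought day 1, 2 and 3 libraries, as total RNA (circles) and mRNA (triangles), 1 library per point. RAB21 goes from 1.50 to 6737 FPKM in total RNA and the Rubisco small subunit gene from 3538 to 15.3.

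The series asks which long noncoding RNAs respond to drought. Of 298 measured noncoding genes, 17 of them shorter than 200 bases, 13 were higher and 5 lower on day 1 (Os03g0660050, Os04g0394766, Os05g0199700, Os05g0368000 and Os06g0480500, named after their values were seen), 32 and 28 on day 2, and 49 and 66 on day 3. Which side was larger on day 3 is not settled, since the counts were 66 and 50 under median-ratio scaling, 54 and 49 under quantile normalization, 32 and 22 with a pseudocount of 5 and 29 and 27 with a mean of at least 5 FPKM. The day 1 count of 13 was 27 with a pseudocount of 0.1, 5 with one of 5 and 7 under median-ratio scaling. On day 3 the main counts were 38.6% of noncoding and 44.2% of protein-coding genes. The correlation of the kinds across noncoding genes was 0.647 on day 1 and 0.922 on day 3. Os06g0318800 (chromosome 6, 12359510 to 12360112), with the highest smaller ratio, was at 21.7 FPKM when watered and at 66.8, 174 and 940 FPKM in total RNA and at 1432 FPKM on day 3 in mRNA. It was followed by Os06g0319133 (listed at 0 when watered in total RNA, 23.5 FPKM on day 3), Os03g0802200 (9.66 and 193 FPKM), Os01g0681900 (5.38 and 88.1 FPKM) and Os01g0795700 (0.296 and 14.8 FPKM). The lowest was Os03g0254250 (chromosome 3, 8134007 to 8134226), at 47.6 FPKM when watered and at 36.3, 2.31 and 0.249 FPKM. Next came Os02g0750200 (57.2 and 2.66 FPKM), Os08g0229200 (47.4 and 2.55 FPKM), Os08g0233000 (34.3 and 0.864 FPKM) and Os01g0221800 (19.7 and 0.945 FPKM). Some of these lie close to a coding gene that was also lower on day 3. Os02g0750200 is 77 bases from one at -4.52 and -4.63, and Os01g0221800 is 101 bases from one at -2.13 and -2.01. For Os03g0802200 and Os01g0681900 the nearest coding gene was not higher, at 0.09 and -0.13 and at -0.43 and -0.25. For Os01g0795700 the nearest coding gene, 3746 bases away, was higher at 4.26 and 3.86. Of the 2 noncoding and coding pairs chosen before the data were examined, the first overlaps by the files' coordinates and the second lies 235 bases apart. Os02g0180800 was at -1.27 and -1.69 on day 3, a call lost under quantile normalization and with a pseudocount of 5, while its partner Os02g0180700, described as cinnamoyl-CoA reductase, was at 1.81 and 1.56. Os02g0250700 was at -0.80 and -1.46, which does not reach the size rule. Its LEA-repeat partner Os02g0250600 was at 1.11 and 1.10, but it is below the expression filter and not 2-fold in both kinds with a pseudocount of 5. The strand setting of the counting is not given in the sources used here, so reads of the first pair may not be separated.

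**Figure D4:**
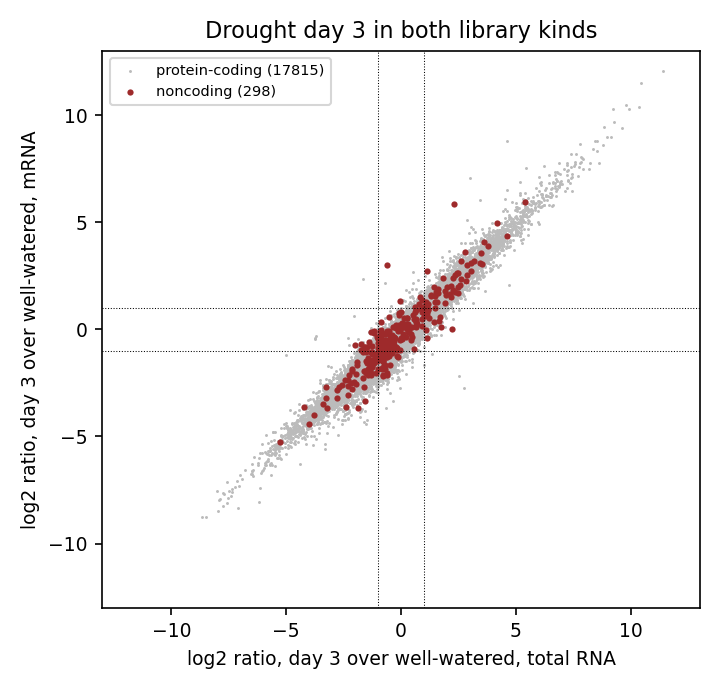
Log2 ratio of drought day 3 over well-watered in the mRNA libraries (y axis) against the total RNA libraries (x axis) for 17815 protein-coding (grey) and 298 noncoding genes (red), dotted lines at 1 and -1. The kinds correlate at 0.974 for protein-coding and 0.922 for noncoding genes.

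The last comparison set total RNA against mRNA libraries under matched treatments, in tables that were normalized separately. The median ratio of total RNA over mRNA was -0.10 ± 0.04 for protein-coding genes and -0.09 ± 0.07 for noncoding genes (log2, SD, n = 4 treatments). Histone genes stood at -0.33 ± 0.05. These medians depend on low genes too, since with no filter they were -0.0372, 0.00897 and -0.18 for protein-coding, noncoding and histone genes, and with a mean of at least 5 FPKM the noncoding one was -0.0130. The histone median was -0.16 with a pseudocount of 5. At least 4-fold under all 4 treatments, 22 genes were higher in total RNA and 65 in mRNA. These counts depend on low genes, being 87 in total RNA with no filter and 4 with a mean of at least 5 FPKM, and 127 in mRNA with a pseudocount of 0.1 and 15 with one of 5. The highest in total RNA were Os04g0473150, described as photosystem II protein D1 (4993 FPKM against 2.00 when watered), and the Rubisco large subunit-like Os01g0791033 (55881 against 9.35), Os10g0356000 (24600 against 4.20) and Os12g0207600 (16319 against 3.01). The plastid genome encodes the proteins these descriptions name. The 10 most abundant genes held 24.3% of summed FPKM in the well-watered total RNA library and 6.76% on day 3, and 11.8% and 6.85% in mRNA.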

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

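The size of difference that brings a gene into this part, the genes named in it, the scaling test and the abundant-gene tests, the comparison of library kinds for RNA breakdown, the share of noncoding genes with an overlap, and the conditions on bootstrap ranges and on clock genes on opposite sides were chosen after the result was seen. Differences between days in this part were not tested, for lack of replicates.

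Some genes were at least 2-fold higher on one drought day and at least 2-fold lower on a later one in both library kinds. There was 1 such gene between days 1 and 2 (Os11g0182200, described as an anthranilate N-benzoyltransferase), and there were 23 between days 1 and 3 and 16 between days 2 and 3. In the other direction, 8 genes were lower on day 1 and higher on day 3, and 4 were lower on day 2 and higher on day 3 (Os01g0695100, Os01g0777900, Os04g0412300 and Os04g0673300). Under median-ratio scaling these counts were 0, 8, 8, 21 and 9 in that order. Lists were first to be compared relative to the median gene, and when aquaporins and cytosolic ribosomal proteins did not reach a difference of 0.5 on both days, single genes were used instead.

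Of the genes higher first and lower on day 3, Os07g0677200 and Os07g0676900 encode peroxidases and ended at 0.787 and 0.138 FPKM in the day 3 mRNA library. The cysteine proteinase gene Os03g0752500 ended at 1.74 FPKM, the proline-rich protein gene Os04g0612500 at 8.10, and Os04g0690800, for the 22 kDa protein of photosystem II, at 74.0 FPKM. The day 1 calls of Os04g0612500 and Os04g0690800 and the day 3 call of the latter were lost under median-ratio scaling. The kinase gene SAPK7 (Os04g0432000) ended at 2.50 FPKM and PIP2-6 (Os04g0233400) at 13.8 FPKM, both day 3 calls being lost under median-ratio scaling and with a pseudocount of 5, as were the day 2 call of SAPK7 and the day 2 and 3 calls of Os07g0676900 with that pseudocount. Of the genes lower first and higher on day 3, the phosphoethanolamine N-methyltransferase gene Os01g0695100 ended at 119.85 FPKM and the A-type response regulator Os04g0673300 at 19.2 FPKM. The noncoding gene Os01g0777900 was at 5.71 FPKM when watered, 1.37 on day 2 and 52.5 on day 3 in mRNA. The earlier lower calls of these 3 genes were all lost with a pseudocount of 5.

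Genes listed in a single table stood outside the comparisons, and only those with a mean of at least 1 FPKM were examined, 13 of 2637 in total RNA and 7 of 880 in mRNA. In the total RNA table, 1 of the 13 was at least 2-fold above well-watered on a drought day, the noncoding gene Os01g0749950 with 3.85 FPKM on day 1 against 0.604. Of the 7 in the mRNA table there were 3, namely Os07g0590700 with 4.87 FPKM on day 3 against 0.440, and the LEA-18 domain genes Os09g0482300 and Os09g0482550 with 4.33 and 5.08 FPKM on day 3, both listed at 0 when watered.

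More genes were 2-fold lower than higher on day 3 with deposited FPKM, with a difference of -1409. Under median-ratio scaling the difference was 920, so the scaling of the libraries may set which side is larger, but with no change of scaling it was also 61 with a pseudocount of 5 and -354 with a mean of at least 5 FPKM, so the weight given to low genes matters too. It was -303 under quantile normalization, and between 520 and 927 for 4 of 5 other gene sets behind the size factors but -137 for genes at 1 FPKM or more in every library. That test was first written for a few abundant genes shifting the scale. The 10 most abundant genes of each library held 24.3% of summed FPKM when watered and 6.76% on day 3 in total RNA, and 11.8% and 6.85% in mRNA. A falling share raises the ratios of other genes, so these shares argue against those genes having made more genes lower. Leaving them out gave -1980, but it could only move the difference down and so adds no test. Which scaling or pseudocount is right cannot be decided from these files, and drought itself stays open and untested.

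Photosynthesis genes were lower on day 3, with pooled medians of 53 of them at -4.68 in total RNA and -4.67 in mRNA. Median-ratio scaling moved these to -4.39 and -4.19, so a shift of scale of that size leaves most of the difference. Leaving out the 10 most abundant genes could only lower the medians, since those genes held a smaller share of summed FPKM on day 3, and so tests nothing here. For harvest at another time of day, LHY minus the mean of PRR1 and GI was at most 0.45 on day 3, inside the bound of 1 set beforehand against that explanation. On day 2, when photosystem genes were already lower, it was 1.93 and 2.10, about the bound of 2 set for that explanation. The measure was a poor one on both days, since GI and PRR1 lie on opposite sides. On day 2 GI was at 0.59 and 0.48 and PRR1 at -2.41 and -2.57, so the day 2 value does not decide either. On day 3 GI was at 1.40 and 0.41 and PRR1 at -0.51 and -1.18. PRR37 and PRR73 stood at -2.01 and -1.80 in total RNA. Of the 10 listed clock genes, 1 was higher, 3 were lower and 6 were not called on day 3, with medians of 0.16 in total RNA and -0.67 in mRNA. For RNA breakdown, the mRNA minus total RNA ratio of the longest genes (at least 2214 bases) less that of the shortest (at most 1046 bases) was -0.25 (bootstrap -0.27 to -0.23), at the bound of -0.25 and short of -0.5, so it does not decide. A test added later, which for a time replaced that one, the photosynthesis median in mRNA minus that in total RNA, was 0.0137 (bootstrap -0.51 to 0.08) against -1 if breakdown were the cause, and its interval crosses the bound of -0.5. Time of day and RNA breakdown cannot be told apart from drought here, and the response to drought stays open and untested.

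Noncoding genes were called in 115 of 298 cases on day 3, and reads shared with an overlapping coding gene could account for some. As the whole cause this is argued against by the 87 called genes, of 234, that overlap no listed coding gene. Of the 64 overlapping genes, 28 were called. The share of called genes with an overlap, 24.3%, was bound to be low, since only 64 of the 298 genes overlap one. That share decides nothing by itself. For the overlapping genes, the mean day 3 correlation with the partner was 0.485 (39 genes with a measured partner). For other noncoding genes with their nearest coding gene it was 0.508 (171 genes), so both groups went with a coding neighbour. The difference of -0.024 was under the bound of 0.1 set beforehand against the explanation. The bootstrap range, a condition added afterwards, is -0.363 to 0.232 and spans that bound, so shared reads cannot be told apart for these 64 genes. The other genes include some close to a coding gene, such as Os02g0750200 at 77 bases, which weakens the comparison. A response to drought stays open and untested.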

How the results depend on the processing

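The quantile-normalized values, the setting without the 10 most abundant genes and the median-ratio factors from other gene sets were chosen after seeing the data. The other alternatives were planned. Of the alternative values of the leading results, 169 stayed within the limits set for their kind and 63 moved. Of those of single genes and lists, 2498 stayed, 2697 moved and 1 reversed, and the cause was not tested unless stated. For named genes there were 276 calls by day, counted without the expression filter. Of these, 276 were kept with a pseudocount of 0.1, 244 with 5, 265 under median-ratio scaling, 262 under quantile normalization and 271 without the 10 most abundant genes. Depth limits low genes most, so a higher pseudocount or filter removes them by construction. A lower pseudocount only enlarges each ratio, so it keeps every call by construction too.

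In the setting limma with library kind as a block the calls numbered 6304 higher and 2369 lower on day 1, 6741 and 5070 on day 2, and 5908 and 9004 on day 3, and for noncoding genes 74 and 32, 72 and 77, and 77 and 158. Limma asks for no 2-fold size and takes the library kinds as replicates, so its counts are higher. With a pseudocount of 5 there were 648 higher and 239 lower genes on day 1, 1643 and 1187 on day 2 and 2511 and 2450 on day 3, which turns the day 3 split to more higher genes, with 5 and 1, 15 and 11, and 32 and 22 noncoding genes, 3 lists higher on day 2, 15 genes 4-fold higher in mRNA and a histone median of -0.16. With a pseudocount of 0.1 there were 27 higher noncoding genes and 4 higher lists on day 1, 127 genes 4-fold higher in mRNA and a histone median of -0.39. With a mean of at least 5 FPKM there were 293 lower genes on day 1 and 2918 on day 3, noncoding counts of 8 and 0, 18 and 14, and 29 and 27, 4 higher lists on day 1, 4 and 28 genes 4-fold apart between kinds and a noncoding median of -0.0130. With no filter 87 genes were 4-fold higher in total RNA, the medians of protein-coding, noncoding and histone genes were -0.0372, 0.00897 and -0.18, and the day 3 total RNA median of aquaporins by description turned from -1.61 to 0.0324.

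Median-ratio scaling gave 677 lower genes, 7 higher and 8 lower noncoding genes and 1 lower list on day 1, and 6 lower lists on day 3. The factors from genes of both tables, genes with a mean of at least 1, filtered genes and genes at 1 or more in every library gave 677, 708, 722 and 754 lower genes on day 1. Quantile normalization gave 765 lower genes, 8 higher and 10 lower noncoding genes on day 1 and 5 lower lists on day 2. The noncoding counts on day 1 were 28 and 8 in total RNA alone and 20 and 8 in mRNA alone. Of the deposited-scale calls, 70.9% of the higher genes on day 1 and 74.2% of the lower genes on day 3 were kept under median-ratio scaling.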

Other observations

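Chitinase and pathogenesis-related genes were higher in 19 of 41 members on day 3 and lower in 5, with medians of 0.89 and 1.00, and the thaumatin-like gene Os03g0663400 was at 1.71 FPKM when watered and 264 FPKM on day 3 in total RNA. Proteases were higher in 9 and lower in 1 of 15 members on day 2 and higher in 8 and lower in 3 on day 3, and the cysteine proteinase gene Os08g0556900 was at 11.0, 184, 490 and 882 FPKM over the 4 treatments. Glutathione S-transferases were higher in 9 and lower in 10 of 29 members on day 3, where the sign of the median differed between scalings. Os10g0528100 of this list was highest on day 2, at 181 FPKM against 3.26. Heat shock proteins and factors were higher in 26 of 130 members on day 1, 40 on day 2 and 32 on day 3 and lower in 2, 9 and 17. Their day 3 medians were 0.20 and -0.02, with a sign that differed between scalings, and the heat shock protein 70 gene Os03g0277300 was at 0.606 FPKM when watered and 110 on day 3. WRKY 45 (Os05g0322900) was at 123 FPKM when watered and 7.95 on day 3, while WRKY 55 (Os03g0321700) was at 0.784 and 46.1 FPKM.

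Sugar transporters were lower in 6 of 9 members on day 3 and higher in 1, with medians of -1.96 and -1.67, and SWEET3a (Os05g0214300) was listed at 0 on day 3 in both kinds. Of 51 cell cycle genes, 4 were higher and 13 lower on day 3. Their total RNA median was -0.26, 0.01 under median-ratio scaling and -0.10 under quantile normalization. In mRNA it was -0.56, -0.11 and -0.17. Of the clock genes, PRR95 (Os09g0532400) was at 125, 76.3, 25.1 and 113 FPKM in total RNA. LHY (Os08g0157600) was at 34.8, 40.8, 71.8 and 52.8 FPKM, and its higher call on day 2 was lost under each other scaling and with a pseudocount of 5. Seed storage protein genes by description were higher in 5 of 11 members on day 3 and lower in none, and a glutelin family gene, Os03g0188500, was at 0.996 FPKM when watered and 92.0 on day 3 in mRNA.

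Shares of transcripts were compared for 2868 genes with at least 2 transcripts that passed a minimum of 5 FPKM for the gene. Of these, 21 had a transcript whose share of the gene moved by at least 50 percentage points from well-watered to day 3 in the same direction in both kinds, and 6 in opposite directions, against 91 genes in total RNA and 132 in mRNA taken alone. The share changes of the kinds correlated at 0.255 across transcripts. Some of the 21 genes did not move steadily. Transcript Os05t0566500-01 held 100, 0.00407, 100 and 0.0108% over the 4 treatments in total RNA, with a like course in mRNA. On day 2 Os03t0275900-01 held 87.2% in total RNA and 21.2% in mRNA, and Os03t0278200-01 held 27.5% and 96.3%. Others, such as Os03g0344100, moved the same way on each day in both kinds. Whether read assignment to transcripts made such swaps was not tested.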
